A study of Drosophila melanogaster with 4 samples.

How the data were processed

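Chromatin-associated RNA was measured in 4 ovary libraries of Drosophila melanogaster, 2 with a germline knockdown of Ars2 and 2 with a germline knockdown of white. Per the labels' protocols, RNA that stays with chromatin was extracted, copied into double-stranded cDNA and tagmented with Tn5, so the libraries do not mark the strand and sense and antisense RNA cannot be told from each other. The submitters' processing notes name FastQC, Trimmomatic, STAR and featureCounts and the dm6 build, and their versions and settings are not given in the sources used here. The deposited values are whole-number read counts per repeat interval, not normalised, per the file headers with the position, name and class of each interval. A suffix in the count column names points to uniquely mapped reads, and no setting that would tell is given in the sources used here. If so, reads that match several copies equally are missing from the counts, and young families with near-identical copies are undercounted. Counts of near-identical copies are uncertain for the same reason.

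The table held 137555 intervals of 9263 repeat names, of which 37327 intervals and 209 names were of the classes LINE, LTR, DNA and RC, called TEs here. In all, 76867 intervals had 0 counts in every library. The column names matched the library titles, and 0 columns were left unused. The totals of repeat-assigned counts, from 262439 to 1544777, are not the depth of the libraries, since reads outside repeats are not in the table. Total counts were lowest in white knockdown library 1, which therefore sets the least precise values. Gene names and bounds came from a table of 17872 RefSeq genes on the same assembly release, and an interval was placed inside a gene when it overlapped the gene's bounds. Exons and introns were not used here. Positions count from 1, as in the deposited table.

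Counts were summed by repeat name into families, and families and single intervals were each fitted in 1 model with all repeat classes. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr at a minimum count of 10, robust estimation and Benjamini-Hochberg adjustment over all rows tested, with a threshold of 0.05. All log2 fold changes are Ars2 over white knockdown, and standard errors come from the same test. The family fit held 2324 rows, of which 186 were TEs, and the interval fit 8948 rows, of which 1429 were TEs. The biological coefficient of variation was 0.410 for families and 0.487 for intervals. Normalised counts per 1000000 (CPM) use the TMM-scaled totals of each fit. For a row at 0 in both controls a fold is given as a lower bound, against 3 counts over the control group. Lists of elements and genes were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists with at least 3 tested rows. Of the 23 lists fixed before the data were examined, the gene lists apply only to repeats inside gene bounds, as the table has no gene rows. GATE, Juan, Stalker, opus, hopper and P-element matched no repeat name.

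The design, the tests, the lists, the alternative settings and the rule for named elements were fixed before the data were examined. The rule named families past the threshold with both Ars2 libraries on 1 side of both controls, 15 rises and 10 falls at most, or the 12 families with the smallest p if fewer than 10 passed, which was the case. It also named the 5 largest rises and 5 largest falls of insertions that passed and were separated, the telomeric families and up to 4 rows per list by p. TOM_I-int, the segment of Myo81F, CG17684 and the split of TART were chosen after the values were seen. The HeT-A sums by chromosome were not fixed in advance either. The sums over these regions were fitted as rows of the family fit. Tests of gene counts and of the targeted genes were not run, since no gene rows were in the table. Alternatives used DESeq2 1.42.0, limma-voom, size factors, library totals, other count filters and TE rows alone. Others used the replicate number as a block or left out each library in turn. Here TE rows alone means a fit without rRNA, simple repeat, low complexity and satellite rows. It kept a few rows of other classes, so 189 of its 194 family rows were TEs. The fit of the 4 TE classes alone is a separate, stricter one.

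The fits were tested on simulated data drawn from the real row means and library totals. All rows of a fit were given its common dispersion, so rows with a larger spread were not simulated. In the family fit, with 200 of 2324 rows changed, 4.55% of 66 rows with 2-fold, 48.4% of 64 with 4-fold and 98.5% of 66 with 16-fold changes were recovered, and 1.00% of the calls were unchanged rows. In the family fit of TE rows alone, with 40 of 194 rows changed, 35.7% of 14 rows with 2-fold and 100% of 13 rows with 4-fold changes were recovered. In the interval fit, with 200 of 8948 rows changed, 0%, 16.7% and 90.3% of rows with 2-fold, 4-fold and 16-fold changes were recovered. In that of TE rows alone, with 200 of 1488 rows changed, the shares were 1.61%, 35.0% and 96.9%.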

Results

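Chromatin-associated RNA, the RNA that stays with chromatin after nuclei are fractionated and is rich in nascent transcripts, was sequenced from Drosophila melanogaster ovaries. Hairpin RNAs against Ars2 were expressed in the germline in 2 libraries, each from a different hairpin line, and a hairpin against white was expressed in 2 libraries from 1 line. Ars2 is an RNA-binding partner of the nuclear cap-binding complex, and white encodes an eye pigment transporter, so its knockdown served as the control. The values are read counts over 137555 annotated repeat intervals of the dm6 build. Repeat-assigned counts summed to 457632 and 1544777 in Ars2 knockdown libraries 1 and 2 and to 262439 and 601576 in white knockdown libraries 1 and 2. Simple repeats took 74.6% and 85.3% of these counts in the Ars2 libraries and 73.4% and 68.5% in the white libraries. Ribosomal RNA intervals took 3.64% and 0.191% in the Ars2 libraries against 7.24% and 12.7% in the white libraries. Exact (Clopper-Pearson) 95% intervals on these shares cover counting error alone, and the widest of them ran from 73.3% to 73.6% for simple repeats in white knockdown library 1. The labels do not say that libraries of a group came from separate cultures or crosses, so the spread between these libraries may be technical. Between the Ars2 libraries it also holds the difference between 2 hairpin lines. Over families of all repeat rows, Ars2 knockdown library 1 correlated more with white knockdown library 1 (Pearson r 0.950) than with Ars2 knockdown library 2 (0.891). The libraries therefore did not group by knockdown in that fit. With TE rows alone the Ars2 pair (0.942) and the white pair (0.964) each exceeded every pair across groups (at most 0.931). With all repeat rows, edgeR took the spread of the median row wholly from a value pooled over rows. Of the 2324 family rows, 2120 were simple repeats. The p-values of these fits therefore do not rest on the spread of each row alone. With TE rows alone the pooling was weaker.

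The knockdown itself was not analysed here. The table holds no gene rows, 0 repeat intervals overlapped Ars2, and the 4 intervals that overlapped white held between 0 and 4 counts per library.

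The first question, named in the title of the series, was whether telomeric retrotransposons and other transposable elements (TEs) gave more chromatin-associated RNA after Ars2 knockdown. HeT-A, TART and TAHRE, the non-LTR retrotransposons that form Drosophila telomeres, all lay higher in both Ars2 knockdown libraries than in either white knockdown library. Every Ars2 library came from another fly stock than the white libraries, so stock and knockdown were not separated, for telomeric copy number as for other loci. HeT-A rose from 292 ± 20.1 to 22950 ± 1484 normalised CPM (counts scaled to library totals; SD, n = 2 per group), a log2 fold change of 6.30 ± 0.64 (SE) with an edgeR adjusted p of 2.8e-19. HeT-A alone made up 17.7% ± 1.12 of all TE counts after Ars2 knockdown and 0.236% ± 0.0329 in the controls (SD, n = 2 per group). The summed counts of the telomeric families rose by a log2 fold change of 4.12 ± 0.57 (SE; edgeR adjusted p = 1.85e-09). TART had a log2 fold change of 1.99 ± 0.54 that just missed the threshold (edgeR adjusted p = 0.0517), TAHRE one of 2.01 ± 0.65 (edgeR adjusted p = 0.189) and the row TART_B1 one of 1.08 ± 0.60 (edgeR adjusted p = 0.532).

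The telomeric increase was assigned to HeT-A and TART copies of the reference outside genes on several chromosomes. Reads from copies that the reference lacks may be assigned to these intervals, so which telomeres gave the RNA is not known. At 2R:25261552-25286841, 4 HeT-A intervals outside annotated genes went from 51.7 ± 5.29 to 8665 ± 2157 normalised CPM (SD, n = 2 per group). HeT-A intervals at X:7022-122492 went from 145 ± 32.3 to 8114 ± 2709, and those at 4:1281471-1320140 from 90.2 ± 6.31 to 6048 ± 826. Each of these sums rose in edgeR, with log2 fold changes of 7.37, 5.81 and 6.06 and adjusted p-values of 9.65e-23, 1.32e-16 and 3.3e-17. Neither this division by chromosome nor the split of TART below was fixed in advance, and their p-values make no allowance for it. TART intervals outside genes, nearly all of their counts from 4:1277575-1281474, rose from 103 ± 39.0 to 3550 ± 344 normalised CPM (log2 fold change 5.13 ± 0.64 SE, edgeR adjusted p = 8.09e-13). The 16 TART intervals inside genes stood at 1018 ± 372 against 1045 ± 416 (log2 fold change -0.04, edgeR adjusted p = 0.989). These intervals supplied most TART counts of the controls, chiefly at X:9678731-9679157 inside nej, so the TART family sum mixes both groups. Their direction was positive when only TE rows were fitted (log2 fold change 0.51, edgeR adjusted p = 0.780). The 7 TART_B1 intervals inside genes, untested as a sum, stood at 129 and 398 normalised CPM in Ars2 knockdown libraries 1 and 2 and at 127 in both controls. HeT-A intervals on Y held 87 and 169 counts against 1 and 3. Ovaries come from females, which normally carry no Y chromosome, so the place of reads assigned there is uncertain.

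**Figure D1:**
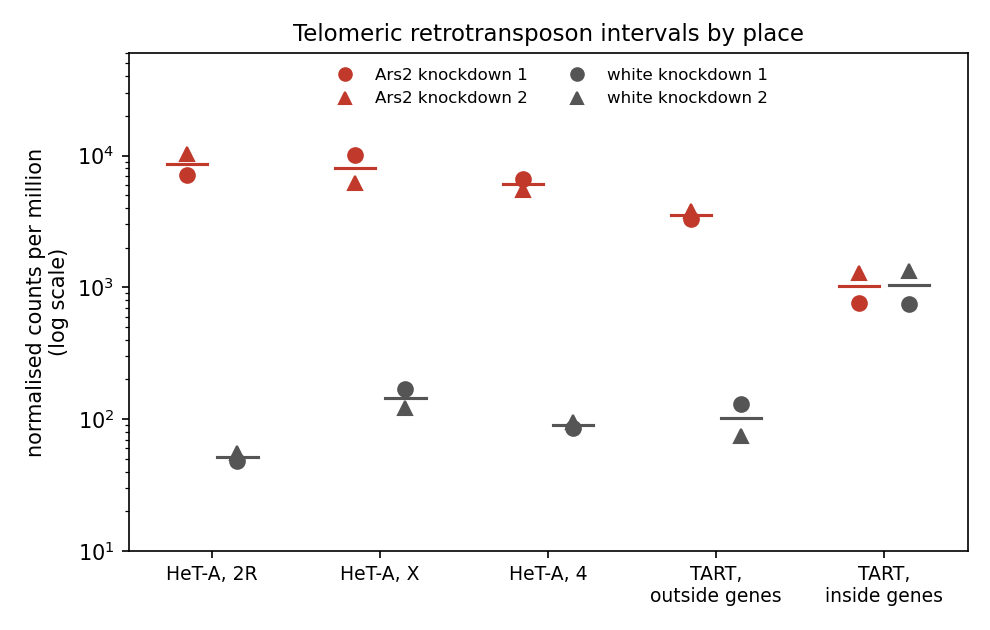
Normalised CPM (log axis) of HeT-A intervals on 2R, X and 4 and of TART intervals outside and inside annotated genes, with a point per library (red Ars2, grey white knockdown, circles library 1, triangles library 2) and a horizontal line at each group mean (n = 2 per group). HeT-A and TART outside genes lie far above the controls in both Ars2 knockdown libraries, while TART inside genes overlaps them at 1018 and 1045.

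Beyond the telomeric families, few TE families passed the test. Of 186 tested, 1 was higher (HeT-A) and 1 lower, BS4_DM, a LINE-type element measured mainly at 1 insertion, which fell from 78.8 ± 43.3 to 11.3 ± 4.23 normalised CPM (SD, n = 2 per group; log2 fold change -2.87 ± 0.75 SE, edgeR adjusted p = 0.0389). At an unadjusted p of 0.05, 21 families passed. The other families among the 12 with the smallest p-values are given as values. Gypsy12_LTR had a log2 fold change of 1.59 and QUASIMODO2-I_DM one of 1.65, the latter mainly from Ars2 knockdown library 1, as the groups overlapped in this fit. With TE rows alone QUASIMODO2-I_DM stood at 2721 and 543 CPM in Ars2 knockdown libraries 1 and 2 against 425 and 436 in the controls. Gypsy_I-int, DIVER_I-int, Baggins1, FROGGER_I-int, DMRT1B and DMRT1C had log2 fold changes between -1.59 and -1.28, with both Ars2 libraries below both controls. None of these passed in edgeR, with adjusted p-values from 0.264 to 0.348. Separation to the lower side was common in this fit, with 90 of the 186 TE families, and is not particular to those named. With TE rows alone it was found in 45 of 189. Simple repeats carried most counts and set the scale, and the median TE family lay at a log2 fold change of -0.42 relative to them. In a fit without rRNA, simple repeat, low complexity and satellite rows this median was 0.01. There, 4 families were higher and 0 lower in edgeR: HeT-A (log2 fold change 6.78, adjusted p = 3.73e-05), TART (2.52, adjusted p = 0.00932), Gypsy12_LTR (7650 ± 1309 against 1936 ± 466 CPM of this fit, SD, adjusted p = 0.00867) and TOM_I-int (1.68, adjusted p = 0.00867), while BS4_DM did not pass (-2.40, adjusted p = 0.060).

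**Figure D2:**
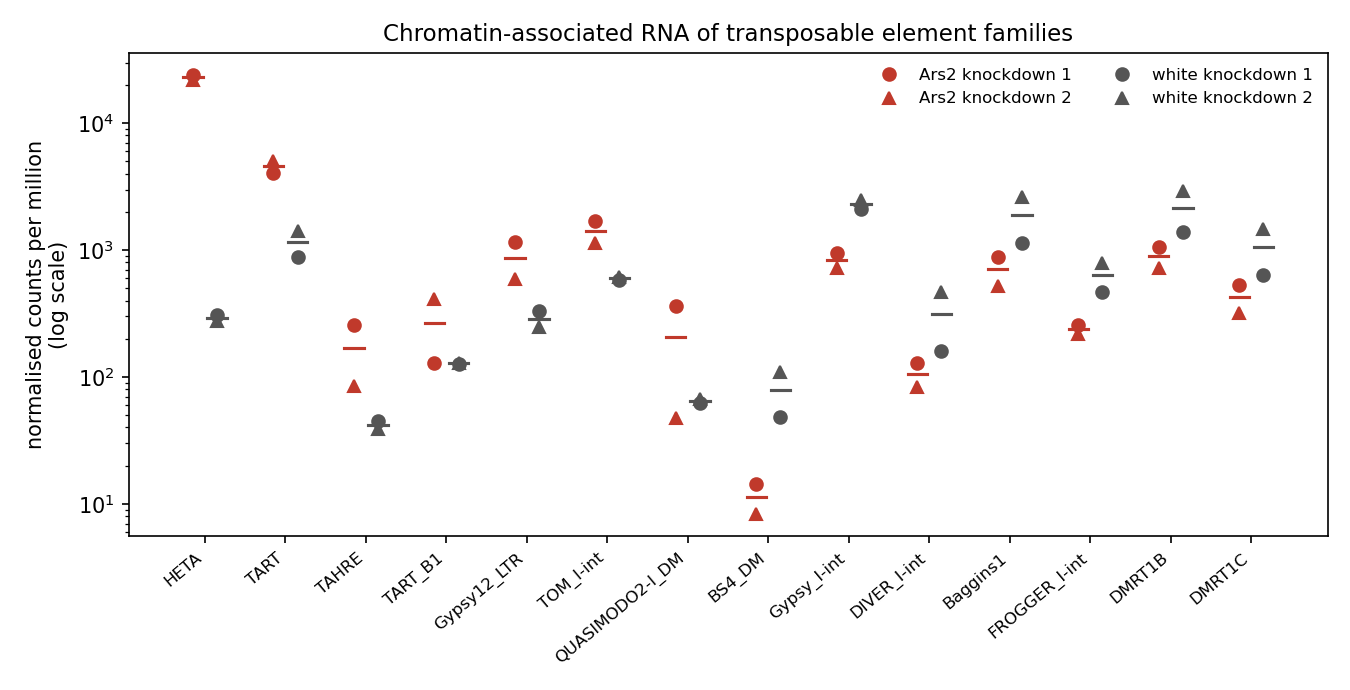
Normalised CPM (log axis) of 14 TE families in each library, with a point per library (red Ars2, grey white knockdown, circles library 1, triangles library 2) and a horizontal line at each group mean (n = 2 per group). HETA stands near 22950 in the Ars2 knockdown libraries against 292 in the controls, and the families on the right lie lower in both Ars2 libraries.

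The family calls depended on both controls. Without white knockdown library 1 or without library 2, 0 families passed in edgeR. The HeT-A log2 fold change stayed between 6.25 and 6.55 over all 4 omissions. HeT-A lost its call without either white library and kept it without either Ars2 library. Every omission left 1 residual degree of freedom, so that number does not set them apart. Without a white library the spread came from the 2 Ars2 libraries alone, which are from different hairpin lines. The summed telomeric log2 fold change was 4.10 without white knockdown library 1 (edgeR adjusted p = 0.638) and 4.38 without library 2 (edgeR adjusted p = 0.999).

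Single insertions showed to which copies of the reference the changes were assigned. Among 1429 tested TE insertions, 27 were higher and 8 lower after Ars2 knockdown in edgeR at an adjusted p of 0.05. Of the 27, 17 belonged to telomeric families and 10 lay inside the bounds of Myo81F, a gene of 1965857 bp in pericentromeric 3R. HeT-A copies at X:116465-122492 and X:96056-101875 held 42 and 291 and 47 and 264 counts after Ars2 knockdown and 0 in both controls. They were therefore at least 41.5-fold and at least 40.2-fold higher, against a floor of 3 counts over the control group that covers counting error only, as reads carried no molecular identifiers (edgeR adjusted p = 2.13e-07 for both). The TART copy at Y:2919780-2922694 held 31 and 86 counts against 0 in both controls (edgeR adjusted p = 0.000208), with the doubt about Y stated above. The HeT-A copy at 4:1281471-1288111 held 264 and 36 counts in Ars2 knockdown libraries 1 and 2 and 0 and 1 in the controls. Its pooled ratio, mostly from library 1, was 135 after scaling, with an exact 95% counting interval from 24.0 to 5340 (edgeR adjusted p = 1.77e-07). The HeT-A copy at 2R:25276106-25280997 had a log2 fold change of 7.59 (edgeR adjusted p = 2.63e-06).

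The Myo81F insertions clustered in a short part of the gene, chosen here after the values were seen. The p-values of its sum make no allowance for that choice. TE intervals on 3R from 0.7 to 1.0 Mb together rose from 841 ± 16.7 to 4221 ± 1170 normalised CPM (SD, n = 2 per group; log2 fold change 2.33 ± 0.55 SE, edgeR adjusted p = 0.0075). The TE intervals in the rest of Myo81F stood at 1843 ± 618 against 2116 ± 288 (log2 fold change -0.20, edgeR adjusted p = 0.940), a direction that turned to 0.20 with TE rows alone. Copies in the segment included Cr1a (DMCR1A), Idefix, Tom, Doc and Gypsy12 sequences. Of all TOM_I-int counts, 81.4% and 81.1% fell inside Myo81F in Ars2 knockdown libraries 1 and 2 and 23.8% and 17.2% in the white libraries. For Gypsy12_LTR these shares were 69.9% and 66.6% against 36.5% and 27.8%, so much of its family rise also lay there. Without intervals that overlap Myo81F, the TOM_I-int log2 fold change was -0.37 among TE rows. The segment sum did not pass without white knockdown library 1 (log2 fold change 2.47, edgeR adjusted p = 0.762) or without library 2 (2.37, edgeR adjusted p = 0.9998). With TE rows alone it passed whichever library was left out, with log2 fold changes from 2.71 to 2.75 and edgeR adjusted p-values up to 0.000664.

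**Figure D3:**
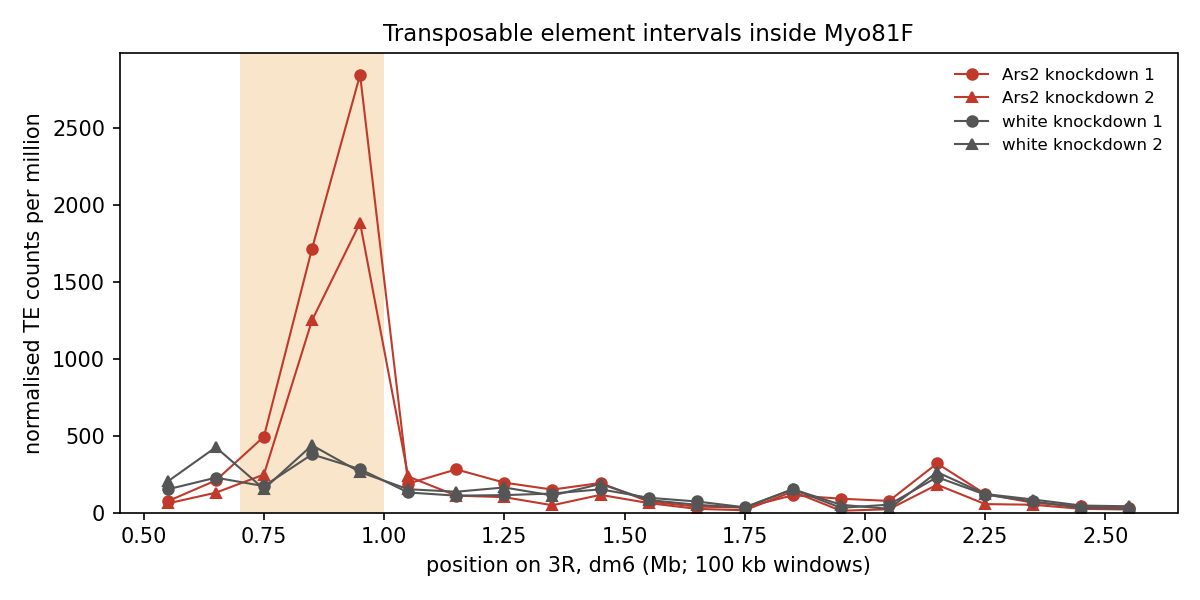
Normalised TE CPM in 100000 bp windows along Myo81F on 3R (dm6, Mb), a line per library, with the segment from 0.7 to 1.0 Mb shaded. Both Ars2 knockdown libraries peak in the shaded part, at 2845 and 1883 in the window from 900001, where the controls stand at 282 and 263.

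Among the 8 lower insertions, 4 lay inside CG17684 (2R:1866080-2262115), 2 outside genes, 1 inside AGO3 and 1 inside Marf1. Marf1 is a germline RNA regulator, and AGO3 encodes a Piwi-family protein. The AGO3 insertion, G_DM at 3L:23600754-23602275, had a log2 fold change of -2.88 (edgeR adjusted p = 0.0278) and was not called with TE rows alone (-2.20, edgeR adjusted p = 0.102). The largest falls were PROTOP_A at 2L:22338411-22339516 in Marf1 (log2 fold change -3.76, edgeR adjusted p = 0.0227), Gypsy2_I-int at 2R:2187981-2188692 (-3.46, adjusted p = 0.0386), BS4_DM at 2R:2191720-2192458 (-3.45, adjusted p = 0.0166), Chimpo_I-int at 2R:2148227-2152276 (-3.45, adjusted p = 0.0237) and DMRT1B at 2R:6456934-6460054 (-3.41, adjusted p = 0.00321). The middle 3 of these lie inside CG17684, and the table does not tell exons from introns. With TE rows alone, 54 insertions were higher and 13 lower of 1483, of which 23 higher ones overlapped Myo81F and 21 were telomeric. Leaving out 1 library moved the count from 35 to between 0 and 93, with 1 without white knockdown library 1, 0 without white knockdown library 2 and 93 without Ars2 knockdown library 1.

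TE groups fixed before the data were examined were then compared. The telomeric list was higher by camera (adjusted p = 1.51e-10, or adjusted p = 0.126 with an estimated correlation), with 1 of 4 rows past the test over all rows and 3 higher when adjusted over the list alone. In the 19 tested rows of germline-type elements, such as DIVER_I-int (-1.59), MDG3_LTR (-1.45), DMRT1B (-1.28) and DMRT1A (-1.15), 0 passed over all rows and 0 adjusted over the list alone. In the 17 rows of follicle-cell-type elements, such as Gypsy_I-int (-1.46), DM176_LTR (-0.94), Gypsy_LTR (-0.73) and Gypsy10_LTR (-0.67), 0 passed either way. The same held for 15 rows of DNA transposons, such as PROTOP_A (-0.91), BARI1 (-0.93), LOOPER1_DM (-0.84) and TRANSIB3 (-0.77), all as log2 fold changes. Camera placed these 3 lists lower, with adjusted p-values of 0.00953, 0.0179 and 0.0108. With an estimated correlation each had an adjusted p of 0.626, and with TE rows alone their adjusted p-values were 0.637, 0.699 and 0.637, so their direction is relative to simple repeats. The 15 rows of intermediate elements had 0 calls (camera adjusted p = 0.506), with log2 fold changes of -0.77 for MDG1_I-int, -0.78 for NOMAD_I-int, 0.79 for Copia_I-int and 0.71 for HMSBEAGLE_I-int. Of the elements that insert into ribosomal DNA, R1_DM stood at -1.35 and R2_DM at -0.31, and R1_DM was lower when adjusted over the list alone (edgeR adjusted p = 0.0489, or 0.0267 with TE rows alone), in libraries whose ribosomal RNA share was also lower after Ars2 knockdown. R2_DM was at 0.19 with TE rows alone. The 5 satellite rows had 0 calls (camera adjusted p = 0.115), with RSP at -1.27, HETRP_DM at -0.60, SAR2_DM at -0.42 and SAR_DM at -0.28. In simulated data with the spread of the family fit of all repeat rows, 4.55% of 2-fold, 48.4% of 4-fold and 98.5% of 16-fold changes were recovered, and 35.7% of 2-fold and 100% of 4-fold changes with that of TE rows alone. Most 2-fold changes of families were therefore not detectable in either fit. All simulated rows of a fit had 1 dispersion, whereas real rows differ in spread, so the shares recovered may be too high. In the real fit of TE rows, log2 fold changes of -2.40 for BS4_DM and 2.36 for TAHRE did not pass (edgeR adjusted p = 0.060 and 0.0551).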

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

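The direction of the telomeric rise did not depend on the processing. The summed telomeric log2 fold change lay between 3.91 and 6.50 over the alternatives. It ranged from 4.10 to 4.38 when 1 library was left out (edgeR adjusted p from 1.69e-34 to 0.999) and from 4.30 to 4.87 for the same with TE rows alone (edgeR adjusted p from 0.00654 to 0.148), at 4.44 without white knockdown library 1 and 4.82 without library 2. Leaving out a white library ended its call in both fits, and leaving out Ars2 knockdown library 2 ended it with TE rows alone (adjusted p = 0.0521). The lone control is then assumed to vary like the Ars2 libraries. The alternatives chosen after seeing the data were those that leave out Myo81F, keep intervals outside genes, keep the 4 TE classes alone, cross the pairing, or combine TE rows with a left-out library or a block.

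The number of TE families called was 2. It was 1 with DESeq2, 1 with limma-voom and 1 with no low count filter. With library totals in place of TMM it was 2, both higher, where the fit with TMM had 1 higher and 1 lower. It was 4 with TE rows alone, 6 with the 4 TE classes alone, 4 with TE rows without Myo81F and 5 with TE rows outside genes. It ranged from 0 to 12 when 1 library was left out and from 0 to 8 for the same with TE rows alone. HeT-A was called under every alternative with all 4 libraries, and 0 families were called without either white library. The number of TE insertions called was 35, and 6 with no low count filter, 15 with a minimum count of 50, 67 with TE rows alone, 67 with the 4 TE classes alone and 22 without Myo81F. It ranged from 0 to 93 when 1 library was left out and from 8 to 145 with TE rows alone, with 73 without Ars2 knockdown library 2. Limma-voom called 38 insertions, 16 higher and 22 lower, and DESeq2 24, 23 higher and 1 lower. Of the lists, 4 were called, and 1, the telomeric list, with no low count filter and in every fit of TE rows. With an estimated correlation none was called, and the telomeric list had an adjusted p of 0.126, or 0.0793 with TE rows alone. When 1 library was left out, the number ranged from 1 to 5. The cause of these shifts was not tested, apart from the smaller number of rows under a stricter filter and of libraries under a left-out one.

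A fit with the replicate number as a block called 1 family, 17 insertions, all higher, and 4 lists, and 4 families, 36 insertions and 1 list with TE rows alone. The labels share only a number across groups, and same-numbered libraries did not deviate together (correlation of deviations -0.09 for families, -0.01 for families among TE rows, -0.06 for insertions and -0.12 for insertions among TE rows). With the numbers crossed, TE rows alone gave 6 families, 75 insertions and 1 list.

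Signs turned for families and regions not called with all repeat rows, of which TOM_I-int was called with TE rows alone. R2_DM had a log2 fold change of 0.19 with TE rows alone and with the 4 TE classes alone, 0.23 without Myo81F among TE rows, 0.18 with the replicate block and 0.16 with the crossed block among TE rows, and from -0.09 to 0.37 among TE rows with 1 library left out. TOM_I-int was at -0.85 without Myo81F, at -0.37 for the same with TE rows and at -0.51 with TE rows outside genes, as its rise lies in Myo81F. With TE rows outside genes, FROGGER_I-int was at 1.02, Gypsy10_LTR at 0.41 and TRANSIB3 at 0.0660. With 1 library left out, QUASIMODO2-I_DM ranged from -0.15 to 2.49, Copia_I-int from -0.31 to 1.51, SAR2_DM from -1.20 to 0.22, SAR_DM from -1.01 to 0.33 and, among TE rows, BARI1 from -0.78 to 0.0744. TART inside genes was at 0.0186 with DESeq2, 0.0187 with its size factors, 0.30 with no low count filter, 0.51 with TE rows alone, 0.52 with the 4 TE classes alone, 0.0416 without Myo81F, 0.52 for the same with TE rows, 0.42 with the block and 0.41 with the crossed block among TE rows. It ranged from -0.47 to 0.57 with 1 library left out and from -0.34 to 1.04 for the same among TE rows, at 0.966 without white knockdown library 2. The rest of Myo81F was at 0.0458 with no low count filter, 0.20 with TE rows alone, 0.21 with the 4 TE classes alone and 0.21 with either block among TE rows. It ranged from -0.31 to 0.11 with 1 library left out and from 0.0921 to 0.32 for the same among TE rows, at 0.152 without Ars2 knockdown library 1. The cause was not tested for these.

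Tests chosen in advance for gene counts, the targeted genes and TMM factors from gene rows were not run, since the table has no gene rows, and camera was not run on the DESeq2 fit. Of simulated 2-fold changes of families, 4.55% of 66 were recovered in the fit of all repeat rows and 35.7% of 14 in that of TE rows alone at the same depth. The simulations also differed in the share of rows changed, 200 of 2324 against 40 of 194. The cause of the difference was not tested, and no other depth was simulated.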

Other observations

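All tests in this part were chosen after the values were seen. The repeats inside gene bounds gave an indirect view of gene expression, with neither exons nor strand known. For some genes the counts were mostly those of TEs. AGO3 held 1401 and 2756 counts in Ars2 knockdown libraries 1 and 2, and TE intervals that overlap it 1354 and 2719. For nxf2 the 35 and 191 counts equalled those of the TART interval at 3L:16576994-16577693. Lists with these genes therefore mix in TE signal. Counts of all repeat intervals except ribosomal RNA that lie inside exactly 1 gene were summed for 2478 genes. In edgeR 0 genes were higher and 4 lower at an adjusted p of 0.05, against 91 higher and 95 lower at an unadjusted p of 0.05. The lower genes were RpS2, a ribosomal protein (log2 fold change -2.48, adjusted p = 0.0387), ds, a cadherin of planar polarity (-2.67, adjusted p = 0.0387), ZnT35C, a zinc transporter (-2.62, adjusted p = 0.0387), whose libraries overlap, and nAChRalpha4, a subunit of an acetylcholine receptor (-2.15, adjusted p = 0.0430). The number of genes called ranged from 0 to 334 when 1 library was left out, so it is set by single libraries.

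For the gene lists fixed before the data were examined, no group change held with an estimated correlation, and Ars2 knockdown library 2 was the lower of the 2 in most members of the lists that fell. All 9 measured follicle cell markers had negative log2 fold changes (median -1.05, 0 called), among them the yolk proteins Yp3 (-1.56) and Yp1 (-1.57) and the chorion gene Cp15 (-1.42), and 3 of the 9 had both Ars2 libraries below both controls, where chance gives 16.7%. Ars2 knockdown library 2 was below library 1 in all 9, with a median log2 ratio to the control mean of -2.82, against -0.48 in library 1, which was below both controls in 3. All 7 muscle markers were negative (median -1.03, 0 called and 3 lower adjusted over the list alone), among them Mhc (-2.02). Library 2 was again below library 1 in all 7, with median log2 ratios of -2.18 and -0.39, and both were below both controls in 6. Of 15 cytoplasmic ribosomal protein genes 14 were negative, 1 was called and 7 were lower adjusted over the list alone, with median log2 ratios of -1.94 in library 2 and -0.79 in library 1, and both libraries were below both controls in 10. Camera placed these lists lower, with adjusted p-values of 8.25e-06, 6.37e-05 and 4.68e-08, and of 0.390 for each with an estimated correlation. The 7 germline markers had a median of -0.03 (camera adjusted p = 0.583) and 9 piRNA pathway genes one of 0.04 (camera adjusted p = 0.973), with 0 called in each. The heat shock list was higher by camera (4 genes, adjusted p = 0.0407, or adjusted p = 0.390 with an estimated correlation), with 1 higher adjusted over the list alone and a median log2 ratio of -0.0997 in library 1, so the rise came from library 2. The 4 genes of the miRNA and siRNA pathway had a camera adjusted p of 0.209, and AGO1 in it had a log2 fold change of 1.39 and was the 1 gene higher when adjusted over the list alone. The lists for hemocytes, DNA damage and telomere capping held 2, 2 and 1 measured genes with 0 called, and those for the cap-binding complex and exosome, histones, snRNAs, snoRNAs, fat body and mitochondrial transcripts held 0.

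In the segment of Myo81F on 3R from 0.7 to 1.0 Mb, all 32 tested TE insertions had both Ars2 libraries above both controls with TE rows alone, with a median log2 fold change of 3.42. The segment was chosen for its raised insertions, and some rows passed the count filter through the Ars2 libraries alone. These values therefore describe the segment and are no separate test of it. On the scale of TE rows, 405 tested copies elsewhere of the same repeat names had a median log2 fold change of 0.0655 (quartiles -0.50 and 0.57). They argue against a rise of the segment's size wherever these names lie. The 14 tested insertions of Myo81F outside the segment had a median of -0.31 (quartiles -1.10 and 0.43). Of these, 1, DM412 at 3R:1228855-1229357, was called higher (11 and 23 counts against 0 in both controls). As a set, these 14 did not share a rise of the segment's size. The bounds were drawn around the raised insertions, which by itself lowers the values left outside. A smaller rise of transcription along the whole of Myo81F therefore cannot be decided from these 14 insertions. A difference between fly lines at this locus, such as an insertion that the reference lacks, cannot be told apart from the knockdown, as 2 of the 2 Ars2 hairpin lines rose and the white line is another stock. Reads assigned here from copies that the reference lacks and an effect of the knockdown stay open, and a control hairpin in the stock of each Ars2 hairpin would be needed to test the latter.

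HeT-A counts were spread differently over copies in the 2 Ars2 libraries, each from its own hairpin line. The copy at X:50787-55026 took 24.2% and 3.83% of HeT-A counts in Ars2 knockdown libraries 1 and 2, and that at 2R:25280996-25286841 took 10.9% and 25.4%. The chi-square per degree of freedom over HeT-A copies was 150 between these libraries and 0.816 between the white libraries, which held only 89 and 170 HeT-A counts. The Ars2 pair thinned to those counts gave a median of 3.58 (95% between 2.19 and 5.41), above the white pair. None of these values decides the cause, as reads without molecular identifiers are not independent and no Ars2 hairpin line has a second library, so counting of duplicate reads, variation between libraries and differences between the telomeres of the lines stay open.

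Inside CG17684, 43 of 46 tested TE insertions had negative log2 fold changes with TE rows alone, with a median of -1.03. The sum of TE intervals there had one of -1.13 (edgeR adjusted p = 0.0153), and with all repeat rows one of -1.51 ± 0.53 (SE, edgeR adjusted p = 0.204). CG17684 was chosen after its lower insertions were seen, and these p-values make no allowance for that choice. The values therefore describe the gene and are no separate test of it. With TE rows alone and 1 library left out the sum ranged from -1.32 to -0.92, and its call depended on which library was left out. On the scale of TE rows, the CG17684 sum stood at 0.46 of the controls. The TE sums of AGO3 and Marf1, which were not tested, also stood lower, at 0.70 and 0.67. A fall particular to CG17684 was therefore not shown. A single high control as the whole cause is argued against by the median without white knockdown library 2, which was -0.77 (quartiles -1.16 and -0.49). Lower expression of the same repeat names wherever they lie, relative to other TEs, is argued against by 291 copies elsewhere. On the scale of TE rows their median was 0.000473 (quartiles -0.74 and 0.43). That scale places TE insertions near 0 (median 0.03), whereas with all repeat rows their median was -0.60. A general fall of TEs relative to simple repeats is therefore not argued against by these copies. Lower transcription of this stretch after Ars2 knockdown and a difference between fly lines both stay open.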
